A study of Homo sapiens with 18 samples.

How the data were processed

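Transcripts were measured by RNA sequencing of 18 libraries from 9 lines of human embryonic stem cells at 2 days, with 1 library per line and day. Per the labels, the cells were H1, H1 with doxycycline, a CTNNB1 knockout of H1, and the knockout with wild-type, S33Y, deltaN90, deltaN148, deltaC or deltaN148C β-catenin. The cells grew on Matrigel in mTeSR1 medium, a feeder-free condition meant to keep them undifferentiated. Endoderm induction was in RPMI medium with B27 and 100 ng/ml activin A. Per the labels' protocols, H1 received 3 µM of the GSK3 inhibitor CHIR99021 on the first day, whereas the knockout and the rescue lines received 0.5 µg/ml doxycycline from 1 day before induction and no CHIR99021. The dose in the H1 library with doxycycline is not stated by the labels. RNA was extracted with TRIzol and the libraries were made for the MGISEQ-2000, per the labels' protocols.

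A single deposited table gave values per gene for all 18 libraries, in 3 units per the file headers: an expected count (the number of fragments the authors' counter assigned to the gene, which need not be whole), FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) and TPM. The authors normalised the deposited FPKM and TPM to gene length and library size. The aligner and the counter are not given in the sources used here. The genome build was GRCh38.p12 per the submitters' processing notes. The table held 18922 genes, named by symbol, and 27 symbols that a spreadsheet had turned into dates were changed back to gene names. TPM entered no comparison. Coordinates in the text are those of GENCODE 29 on GRCh38. Reads shared between near-identical copies, such as the MTRNR2L genes, the histone genes or SERF1A and its copies, may have been divided between them, so their values are uncertain. Strand use is not stated, so reads of overlapping antisense genes are included where present.

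The libraries held 13940756 to 15412758 expected counts. A count of 3 at a gene of median length is an FPKM of 0.063 to 0.070, a conversion and not a Poisson limit. Intervals given in the text are exact Poisson ones at 95% that cover counting error only. Genes were kept when their FPKM was at least 1 in at least 2 of the 18 libraries, which left 13633. This filter ran over all 18 libraries for every comparison of single libraries. The tests across the 6 rescue lines applied it within the libraries of the fit and kept 12729 genes at day 0 and 12843 at day 1.

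Values were compared as log2(FPKM + 1). The groups have 1 library each, so comparisons between single lines carry no test and no p. A gene counted as different when the log2 difference was at least 1, and in comparisons with wild type it had to pass in the same direction against H1 and against H1 plus Dox, the mean of both differences being printed. The β-catenin-dependent response genes were those higher at day 1 in both wild-type lines whose rise in the knockout was smaller by at least 1 than in both. For each rescue line, the line's own day 1 minus day 0 difference was divided by the mean of the wild-type differences, and the median over the genes was taken. To say whether a gene list stood apart, its median was placed among those of 10000 random lists of the same size matched on mean expression in 20 bins. This percentile describes these libraries and is not a test.

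The change between days was tested with limma 3.58.1 (lmFit, eBayes with trend and robust) in R 4.3.3, with the line as a block and so 8 residual degrees of freedom. The 9 lines stand in for replicates although their genotypes differ, so the spread includes real differences between lines. H1 and H1 plus Dox count as separate lines, although the labels do not state whether they were separate cultures. Only H1 and H1 plus Dox received CHIR99021, so the tested change pools different treatments. The parts of the β-catenin protein were tested with limma over the 6 rescue lines at each day, with 3 features in 1 additive model: the C terminus kept, residues 91 to 148 kept, and the N-terminal phosphorylation sites lost. S33Y, which is changed at a site and not deleted, was counted with the N-terminal deletions as having lost the sites. Residue numbers were read from the construct names in the labels. These tests were two-sided and adjusted by the Benjamini-Hochberg method over all genes tested, with 0.05 as the threshold. Counts adjusted over a list alone used the same p-values. Gene lists were also tested between days by an exact sign-flip permutation test of their mean difference over the 9 lines (512 sign patterns, two-sided, adjusted over 24 lists).

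FPKM with limma was the planned main test and stayed so, since the design had been fixed on normalised values. After the expected counts were seen, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were added as alternatives, on expected counts rounded to whole numbers. Also added after the data were examined were counts without the MTRNR2L genes and the recovery of the day 1 level against the H1 day 0 level. The groups, the tests, the gene lists, the named-gene rule and the other alternatives were chosen before the data were examined. Those alternatives were a pseudocount of 0.5 in place of 1, no filter, a mean FPKM of at least 5, libraries rescaled by the median ratio to the geometric mean library (10877 genes with FPKM above 1 in every library), no line block, no trend or robust option, each line left out in turn, 2 features in place of 3, the day difference as outcome, H1 or H1 plus Dox as the only reference, and the ratio of means for recovery. Tests were run on simulated data first: with 200 of 13158 genes changed, the day test recovered 100.0% at log2 changes of 1 and of 2, with 19 false calls, and the C-terminus test at day 1, with 199 of 12877 changed, recovered 48.9% at 1 and 100.0% at 2, with 13 false calls. The simulated spread between lines was the same for every gene, and genes that vary more are recovered less often than this. It was also the same on both days, so the line block of the day test removed it. No difference between lines in the day change was simulated, so the 100.0% does not give the recovery of the day test in the real data.

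The genes named are CTNNB1, TBXT, MIXL1, EOMES, GSC, SOX17, FOXA2, CXCR4, AXIN2, LEF1, SP5, POU5F1, SOX2 and NANOG in every comparison; up to 4 members of each list with the largest absolute difference among those that passed; and the 8 largest rises and 8 largest falls among genes that passed and reached an FPKM of 5 in a library compared. The lists covered pluripotency, Wnt targets, primitive streak, definitive endoderm, Nodal and activin feedback, mesoderm, early neural, neural crest, amnion and trophoblast, mesenchyme, endothelium and blood, adherens junction, epithelial-mesenchymal transition, Wnt pathway components, sterol synthesis, integrated stress, p53 targets, hypoxia and glycolysis, proliferation, FGF and ERK response, BMP targets, HOX, histone and housekeeping genes. Of 394 listed members 371 were in the table. A further list of transcripts of the mitochondrial genome had no member in the table, so 24 of 25 lists were used. Tables and plots were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.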

Results

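The data were 18 RNA sequencing libraries of H1 human embryonic stem cells and of cells derived from them in which the gene for β-catenin, CTNNB1, had been knocked out. β-Catenin is the transcriptional coactivator of canonical Wnt signalling and also a component of adherens junctions. There were 9 lines: H1, H1 with doxycycline (H1 plus Dox), the CTNNB1 knockout, and 6 rescue lines in which the knockout carried a doxycycline-inducible β-catenin. The rescue constructs were wild-type β-catenin, S33Y (a change at an N-terminal phosphorylation site that marks the protein for degradation), deltaN90 and deltaN148 (which lack the N terminus to different extents), deltaC (which lacks the C-terminal transactivation domain) and deltaN148C (which lacks both ends). Each line was sequenced before induction (day 0) and after 1 day of definitive endoderm induction with 100 ng/ml activin A (day 1). H1 and H1 plus Dox also received the GSK3 inhibitor CHIR99021 (3 µM) on that day, and the other lines did not. Each line and day was 1 library, so there were no replicates. The libraries held 13940756 to 15412758 assigned fragments, and 3 fragments on a gene of median length corresponded to an FPKM of 0.063 to 0.070. Between 12058 and 12985 genes per library had an FPKM of at least 1.

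CTNNB1 itself, on chromosome 3 (41194741 to 41260096, plus strand, GRCh38), was measured at an FPKM of 104 in H1 and 120.0 in H1 plus Dox at day 0, and at 81.3 and 79.5 at day 1. The knockout retained CTNNB1 transcript at 20.2 (95% Poisson interval 18.953 to 21.550, counting error only) at day 0 and 29.97 at day 1. The wild-type rescue carried 1291 at day 0 and 710.2 at day 1, and the deltaC rescue 689.9 and 554. S33Y had 458 and 487, and deltaN90 had 222 and 327. The deltaN148C rescue had 119 and 124, and the deltaN148 rescue had 41.8 and 53.4, the lowest of the 6 rescue lines on each day. These values follow the labels, since every rescue library lay above the knockout library of the same day. The transcript that the knockout retained may be part of the rescue values, because counts per gene do not separate it from the construct. The level of the construct alone is therefore not known. This matters most for deltaN148, whose values were closest to those of the knockout. The deposited FPKM was normalised to gene length. If that length was not adapted to the construct, which is not stated, the values of truncated constructs are understated relative to full-length ones.

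**Figure D1:**
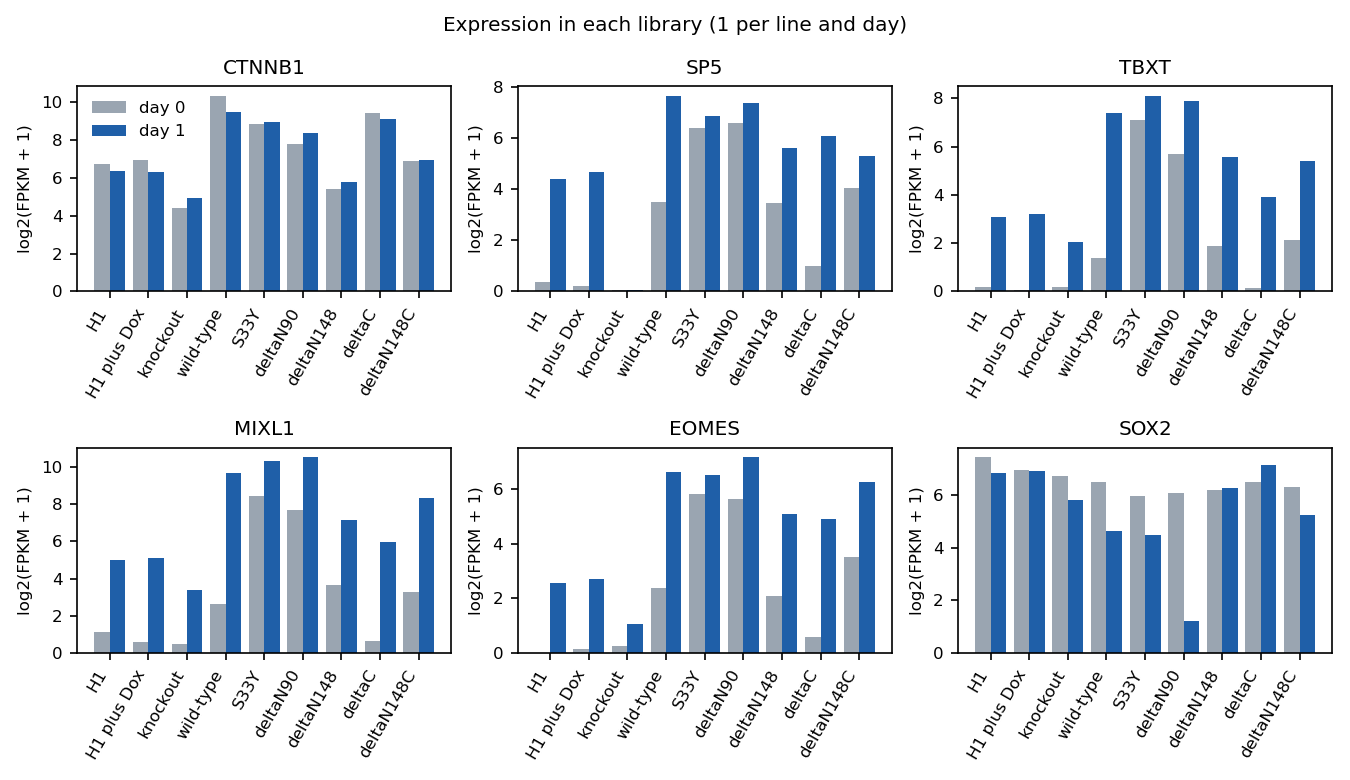
Bars give log2(FPKM + 1) of CTNNB1, SP5, TBXT, MIXL1, EOMES and SOX2 in each of the 18 libraries, grey for day 0 and blue for day 1, with 1 library per bar and no error. At day 1 MIXL1 reached an FPKM of 804 in the wild-type rescue against 9.38 in the knockout, and SOX2 was 1.31 in the deltaN90 rescue.

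The first comparison asked what 1 day of endoderm induction changed in wild-type cells. This day brought activin A, CHIR99021 and a change of medium from mTeSR1 to RPMI with B27, and their effects are not separated. Several genes of Nodal signalling and of the primitive streak, the embryonic site where mesoderm and endoderm arise, had higher levels at day 1 in H1 and in H1 plus Dox alike. The growth factor gene FGF8 went from an FPKM of 0.70 to 106 in H1, the Nodal antagonists LEFTY1 and LEFTY2 from 1.76 to 169 and from 2.24 to 274, and NODAL itself from 5.70 to 149. The streak transcription factors MIXL1 (1.14 to 31.2), EOMES (listed at 0, then 4.99) and TBXT, also called brachyury (0.12 to 7.54), were higher at day 1, as was the Wnt-induced factor SP5 (0.28 to 20.3). The core pluripotency gene POU5F1 stayed at 1493 and 1562, and the endoderm regulators SOX17 and FOXA2 were still at 0.09 and 0.17 at day 1.

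By the rule of a log2 difference of at least 1 in the same direction in H1 and in H1 plus Dox, 201 genes were higher at day 1 and 142 were lower. Of 11 genes of Nodal and activin feedback, 7 were higher, with the list's median at the 100th percentile of random lists of similar expression. They included CER1, a secreted Nodal and BMP antagonist of anterior endoderm (mean log2 difference 4.81, a gene also listed under endoderm). Of 17 primitive streak genes 7 were higher, WNT3 by 3.41, although the list's median lay at the 90.7th percentile. Of 19 Wnt targets 4 were higher, namely SP5 (4.26), the Wnt deacylase NOTUM (2.18), CCND1 (1.97) and TCF7 (1.27). Of 17 genes of the integrated stress response 3 were higher, among them TRIB3 (2.94) and DDIT4 (2.05), and of 13 BMP targets 2 were, among them ID2 (1.61). Sterol synthesis went the other way, with 4 of 18 genes lower and none higher, among them INSIG1 by -2.33, FDFT1 by -1.62 and MSMO1 by -1.45. Lower outside the lists were the Wnt antagonist SFRP1 (-3.04), the thioredoxin inhibitor TXNIP (-2.96), the metallothionein MT1X (-2.89) and IDO1 (-2.42). Among pluripotency genes DNMT3B (-1.31), TDGF1 (-1.20) and THY1 (-1.42) were lower, 3 of 24. No test was run on this comparison, which had 1 library per line and day. H1 plus Dox alone gave 574 higher and 315 lower genes, and H1 alone 289 and 432, so the requirement that both pass set the size of the list.

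H1 plus Dox against H1 served as a yardstick for a pair of wild-type libraries. The labels do not say whether these were separate cultures, and any effect of doxycycline is part of the difference. At day 0 the pair differed more than at day 1. At day 0, 58 genes were higher and 238 lower in H1 plus Dox. The lower ones included the metallothioneins MT1E (-3.47), MT1G (-3.22) and MT2A (-3.12), TXNIP (-3.42), the stress genes DDIT3 (-2.58), DDIT4 (-2.13) and TRIB3 (-1.55), and the hypoxia-induced gene BNIP3 (-1.98). LEFTY1 (2.27), CER1 (1.93) and HMGCS1 of sterol synthesis (1.62) were higher. At day 1 the corresponding counts were 8 and 4, SERF1A being the largest at 1.83, and the correlation across genes, which are not independent replicates, was 0.978 at day 0 and 0.997 at day 1. The standard deviation of the log2 difference was 0.389 at day 0 and 0.152 at day 1.

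Loss of β-catenin was first compared with wild type in undifferentiated cells. The 3 core pluripotency factors were near their wild-type levels: POU5F1 was at 1337 in the knockout against 1493 and 1226, SOX2 at 103 against 171 and 123, and NANOG at 89.5 against 78.7 and 75.9. LEFTY1 was higher in the knockout (50.2, against 1.76 in H1 and 12.3 in H1 plus Dox), as were LEFTY2 (15.6) and NODAL (24.4). ERVH48-1, which encodes a retrovirus-derived envelope protein, was at 8.62 in the knockout against 167 and 136.

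Altogether 43 genes were higher and 99 lower in the knockout at day 0 than in both wild-type libraries. CTNNB1 was among the latter (-2.41). Large falls were those of ERVH48-1 (-3.98), the secreted ribonuclease RNASE1 (-3.38), the serotonin receptor HTR7 (-3.30), the kinase CDK10 (-3.01), the esterase IAH1 (-2.90), the zinc finger gene ZNF492 (-2.75) and MEF2B (-2.62). Among the genes higher in the knockout were the histone gene HIST1H2BK (3.22), LEFTY1 (3.08), the smooth muscle actin ACTG2 (2.26) and LCP1, an actin bundling protein (2.19). Of 11 Nodal and activin genes 3 were higher, with the list's median at the 99.99th percentile (0.64). Of 17 integrated stress genes 3 were lower, DDIT4 by -2.70, CHAC1 by -1.69 and PCK2 by -1.53 (percentile 0.00). None of 18 sterol genes passed, although their median was 0.70 higher (percentile 100.0). None of 19 Wnt targets passed. Against H1 alone 188 genes were higher and 738 lower, and against H1 plus Dox alone 78 were higher and 132 lower.

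At day 1 more genes differed from both wild-type libraries, with 222 higher and 537 lower in the knockout. The correlation across genes between the knockout and H1 was 0.96 at day 0 and 0.959 at day 1. With H1 plus Dox it was 0.982 and 0.957. The wild-type pair also differed less at day 1, which lets more genes pass against both. Wild-type cells received the GSK3 inhibitor CHIR99021 (3 µM) during the day of induction and the knockout did not. The day 1 difference from the knockout therefore contains that of the treatment as well as that of the genotype. Wnt targets and streak genes were lower. SP5 was at 0.05 in the knockout against 20.3 and 24.5, TBXT at 3.08 against 7.54 and 8.28, MIXL1 at 9.38 against 31.2 and 33.5, and EOMES at 1.11 against 4.99 and 5.63. SOX2 was at 55.6 against 112 and 118.

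Of 19 Wnt targets 6 were lower and none higher (percentile 0.00), including SP5 (-4.47), NOTUM (-2.06), AXIN2, the feedback gene used as a standard readout of the pathway (-1.93), and CCND1 (-1.66). Of 17 streak genes 5 were lower (percentile 0.04), including FGF8 (-2.52) and GAD1 (-2.19). Of 11 Nodal and activin genes 2 were lower, one being the SMAD partner FOXH1 (-2.25), and of 15 p53 targets 6 were, including GDF15 (-2.91), BBC3 (-1.68) and CDKN1A (-1.47). Integrated stress genes (5 of 17 lower, TRIB3 by -1.69) lay on the same side. Sterol genes were higher in the knockout, 13 of 18 with none lower (percentile 100.0), including HMGCS1 (2.82), IDI1 (2.42) and INSIG1 (2.13). The housekeeping list was also shifted upward (median 0.43, percentile 99.57), with 1 of 14 genes passing. Other genes on the higher side were the ERK phosphatase DUSP6 (3.06), the Notch target HEY1 (2.85), the metallothionein MT1H (3.14) and the pluripotency genes DPPA2 (2.21) and GDF3 (1.87). Among the lower ones were the transcription factor HES3 (-3.53) and the activin antagonist FST (-3.18), besides ERVH48-1 (-4.95) and HTR7 (-3.77), which were lower at day 0 too.

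A set of β-catenin-dependent response genes was defined on the wild-type and knockout libraries alone: genes that rose in H1 and H1 plus Dox and whose rise in the knockout was smaller by at least 1 on the log2 scale. The wild-type lines received CHIR99021 at day 1 and the knockout and rescue lines did not, so dependence on β-catenin and on the inhibitor are not separated in this set or in the shares below. There were 86, among them FGF8, LEFTY1, LEFTY2, NODAL, SP5, the actin-binding protein FLNC, TBXT, EOMES, GAD1, NOTUM, GATA4, CCND1 and CYP26A1, a retinoic acid hydroxylase. They included 5 of 17 streak genes and 4 each of the 19 Wnt targets and the 11 Nodal and activin genes. The rule is on the rise, so a gene that began higher in the knockout at day 0 can meet it. LEFTY1, LEFTY2 and NODAL began higher there, and at day 1 LEFTY1 was higher in the knockout than in H1. Membership therefore does not show that the day 1 level was lower without β-catenin. The rescue lines took no part in choosing the 86 genes. The share of the wild-type day 1 rise that each line made, as the median over the 86 genes, was 0.423 in the deltaN148C rescue, 0.416 in the wild-type rescue, 0.395 in deltaN148, 0.347 in deltaC, 0.179 in S33Y and 0.067 in deltaN90. The knockout made 0.054, a low value that follows from how the genes were chosen, and H1 and H1 plus Dox, which defined the scale, 0.934 and 1.07. In 36 of the 86 genes the wild-type rescue rose by at least 1, against 31 in deltaN148 and deltaN148C each, 23 in S33Y, 22 in deltaC, 20 in deltaN90 and 7 in the knockout.

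The low values of S33Y and deltaN90 belonged to lines in which many of the genes were already high at day 0. When the day 1 level was set against the H1 day 0 level in place of the line's own, a measure added after the data were examined, the median was 0.680 in deltaN90, 0.560 in deltaN148C, 0.526 in the wild-type rescue, 0.396 in S33Y, 0.367 in deltaN148, 0.280 in deltaC and 0.117 in the knockout. On this added measure S33Y still lay below deltaN148C and the wild-type rescue. The spread of the first measure between the wild-type lines was 0.131. The order of the rescue lines by that measure depended on the reference. With H1 plus Dox as the only wild-type reference the set grew to 224 genes, and the medians were 0.414 in deltaN148C, 0.383 in deltaN148, 0.289 in deltaC, 0.242 in the wild-type rescue, 0.215 in S33Y and -0.023 in deltaN90. With H1 as the only reference they were 0.442 in deltaN148C, 0.484 in deltaN148, 0.227 in deltaC, 0.222 in the wild-type rescue, 0.213 in S33Y and 0.072 in deltaN90, so the gap between the wild-type rescue and S33Y was smaller under either single reference.

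Wild-type β-catenin was the construct that asked whether re-expression restores the response of the knockout without CHIR99021. At day 1 the wild-type rescue exceeded the knockout in streak and endoderm genes by wide margins: MIXL1 was at 804 against 9.38, TBXT at 167 against 3.08, EOMES at 97.8 against 1.11 and SP5 at 199 against 0.05. These were also above the H1 levels of the same day. FOXA2, a pioneer factor of endoderm, was at 23.5 against 0.12, the highest value of any library. GSC was at 16.8 against 0.26, and SOX17 was at 1.17 and listed at 0 in the knockout. The antagonists LEFTY1 and LEFTY2, in contrast, were at 17.2 and 9.43 in the wild-type rescue against 210.4 and 139.8 in the knockout.

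In all, 362 genes were higher and 324 lower in the wild-type rescue than in the knockout at day 1, and 34 and 43 at day 0. At day 1 the higher genes took in 15 of 17 streak genes, 11 of 19 Wnt targets, 8 of 15 endoderm genes, 8 of 16 mesoderm genes and 8 of 12 HOX genes, the medians of all 5 lists lying at the 100th percentile. They included SP5 (log2 difference 7.58), the Wnt antagonists DKK1 (6.44) and DKK4 (5.57), EVX1 (5.52), FGF17 (5.17), the caudal factor CDX2 (3.997) and GATA6 (3.49). Of 24 pluripotency genes 7 were lower and 2 higher, PRDM14 by -2.01, TERF1 by -2.01 and SOX2 by -1.19. Also lower were LEFTY2 (-3.75), LEFTY1 (-3.54), HEY1 (-3.25), the Wnt receptor FZD5 (-2.48) and the Wnt repressor TCF7L1 (-1.59), and of 11 Nodal and activin genes 4 were lower and 3 higher. At day 0, when doxycycline had been present for 1 day, the higher genes were CTNNB1 (5.93), SP5 (3.42), MIXL1 (2.17), EOMES (2.11), GAD1 (1.88) and TBXT (1.21), along with the MTRNR2L genes, nuclear copies of a mitochondrial RNA gene, and the interferon-induced IFIT1 (-1.42) and IFIT2 (-1.48) were among the lower ones.

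The S33Y construct, changed at a phosphorylation site that leads to degradation, and deltaN90, which lacks part of the N terminus, asked what stabilised β-catenin does. In the S33Y and deltaN90 lines many streak and Wnt target genes were already high before induction with activin A. At day 0 MIXL1 was at 343 in S33Y and 205 in deltaN90 against 0.38 in the knockout and 5.21 in the wild-type rescue, TBXT at 136 and 50.1 against 0.13 and 1.61, LEF1 at 16.7 and 20.4 against 0.13 and 1.34, and AXIN2 at 54.7 and 53.7 against 6.91 and 9.95. At day 1 mesoderm genes joined them: MSGN1, of the presomitic mesoderm, was at 84.3 in S33Y and 35.7 in deltaN90 and at 0.06 in the knockout, and HAND1, of lateral and cardiac mesoderm, at 217 and 36.3 against 0.17. In deltaN90 at day 1 SOX2 was at 1.31 against 55.6 in the knockout and NANOG at 21.9 against 126, while POU5F1 was at 647 against 1456.

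Against the knockout, S33Y had 253 genes higher and 68 lower at day 0 and 567 and 259 at day 1. The day 0 set took in 13 of 19 Wnt targets, 11 of 17 streak genes and 10 of 12 HOX genes, including MIXL1 (7.96), TBXT (6.92), SP5 (6.32), DKK4 (5.65), CDX2 (5.10) and FOXA2 (3.36), with LCP1 (-2.10) and TCF7L1 (-1.16) lower. The day 1 set took in 15 of 16 mesoderm genes, 12 of 12 HOX genes, 10 of 13 BMP targets, 14 of 17 streak genes and 14 of 19 Wnt targets, with 11 of 24 pluripotency genes lower. Its largest members were DKK1 (8.50), DKK4 (7.91), the apelin receptor APLNR (7.88), HAND1 (7.54) and MSX1 (7.02), and it included GATA6 (6.62), the mesenchymal factor SNAI2 (5.29), BMP4 (4.22) and CXCR4 (3.55). The metallothioneins MT1E (-2.72) and MT1X (-2.62) were lower.

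The deltaN90 rescue had 206 genes higher and 210 lower than the knockout at day 0, and 665 and 958 at day 1, the largest day 1 total of the 6 rescue lines. At day 0, 13 of 19 Wnt targets and 8 of 17 streak genes were higher, and 6 of 24 pluripotency genes lower, PRDM14 by -1.99 and DNMT3B by -1.72. At day 1 all 16 measured mesoderm genes, 14 of 19 Wnt targets, 13 of 17 streak genes and 9 of 11 genes of epithelial-mesenchymal transition were higher, and 14 of 24 pluripotency genes were lower. DKK1 (9.001), DKK4 (8.71), APLNR (7.46), MESP1 of nascent mesoderm (5.71), CER1 (4.47) and SOX17 (3.94) were higher, and SOX2 (-4.61), PRDM14 (-3.59), FZD5 (-3.62), TCF7L1 (-3.47) and NANOG (-2.48) lower. Sterol genes were higher in this line (7 of 18, HMGCS1 by 1.55) and integrated stress genes lower (6 of 17, CHAC1 by -1.70).

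The deltaN148 rescue, which lacks a further N-terminal segment that deltaN90 keeps, had 289 genes higher and 207 lower than the knockout at day 0, and 183 and 182 at day 1. At day 1 it had 8 of 17 streak genes and 7 of 19 Wnt targets higher, with SP5 at 47.6 against 0.05 (log2 difference 5.53), EOMES at 33.1 (4.02), MIXL1 at 141 (3.77) and TBXT at 46.5 (3.54). Only 2 of 16 mesoderm genes were higher. Its CTNNB1 level of 53.4 stood below that of H1. Hypoxia and glycolysis genes were high on each day, 11 of 17 at day 0 (median 1.30) and 12 of 17 at day 1 (median 1.25). The glucose transporter SLC2A1 was at 337 and 367 against 90.1 and 103 in the knockout, BNIP3 at 141 and 113 against 15.5 and 14.9, and the lactate exporter SLC16A3 at 28.6 and 22.3 against 1.97 and 1.94. ANXA1 was lower at day 0 (-3.38), as were HHLA1 (-3.03) and 6 of 24 pluripotency genes, and at day 1 5 of 18 sterol genes were lower, IDI1 by -1.72.

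Removal of the C terminus was represented by deltaC and deltaN148C. The deltaC rescue left undifferentiated cells close to the knockout in streak genes, none of 17 passing at day 0, when 25 genes were higher and 85 lower. At day 1 it had 180 higher and 237 lower. SP5 was at 65.8 against 0.05 (5.99), EOMES at 28.8 (3.82), MIXL1 at 62.3 (2.61) and TBXT at 13.8 (1.86), with 6 of 17 streak genes and 6 of 19 Wnt targets higher and 2 Wnt targets lower. SOX2 was higher, at 140.5 against 55.6 (1.32), and SOX17 was listed at 0. Of 11 Nodal and activin genes 5 were lower and none higher, LEFTY1 at 12.2 against 210.4 (-3.998) and LEFTY2 at 10.6 against 139.8 (-3.60), and CER1 was at 17.6 against 73.8 (-2.01). At day 0 the lower genes included CSAG2 (-2.70) and the interferon-induced IFIT1 (-2.45) and IFIT3 (-2.40).

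The deltaN148C rescue, without either end, had 58 genes higher and 70 lower at day 0 and 118 and 80 at day 1. At day 1, 11 of 17 streak genes, 8 of 15 endoderm genes, 6 of 19 Wnt targets and 3 of 11 Nodal and activin genes were higher. MIXL1 was at 325 (4.97), EOMES at 76.8 (5.204), TBXT at 41.4 (3.38), GSC at 11.2 (3.27) and FOXA2 at 6.27 (2.70). Hypoxia and glycolysis genes were higher in 4 of 17, and IFIT1 (-2.08) and ISG15 (-1.95) were lower. IFIT1 lay below the knockout in each of the 6 rescue lines: at day 0 it was at 52.8 in the knockout and between 8.15 and 23.2 in the rescues.

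Pairs of constructs that differ in a single part were then set side by side, a comparison added after the rules for the others had been fixed. With the C terminus present (wild-type minus deltaC), 38 genes were higher and 19 lower at day 0, and 236 and 87 at day 1. At day 1, 16 of 17 streak genes (median 1.94), 8 of 15 endoderm genes, 8 of 12 HOX genes and 8 of 19 Wnt targets were higher, including DKK1 (6.04), FGF17 (4.29), MIXL1 (3.67), TBXT (3.50), GATA6 (3.14) and FOXA2 (3.00), and SOX2 (-2.51), SFRP1 (-2.64) and TCF7L2 (-1.67) lower. CTNNB1 itself was higher in the wild-type rescue at both days. Without the N terminus (deltaN148 minus deltaN148C) part of these genes went the other way at day 1. In the line that kept the C terminus 8 of 17 streak genes and 4 of 15 endoderm genes were lower, FGF17 by -2.46, GSC by -2.22, GATA6 by -2.03 and MIXL1 by -1.20. CTNNB1 was also lower there (-1.20), and 68 genes were higher and 92 lower. TBXT (46.5 in deltaN148 against 41.4 in deltaN148C), SP5 (47.55 against 37.96) and the mean of the Wnt targets (2.93 against 2.86) were not lower.

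With that N-terminal segment present (deltaN90 minus deltaN148), 500 genes were higher and 776 lower at day 0 and 811 and 1124 at day 1, the largest totals of these pairs. At day 1, 15 of 16 mesoderm genes and 16 of 18 sterol genes were higher, 11 of 17 hypoxia genes and 13 of 24 pluripotency genes lower, and CTNNB1 was higher by 2.59. S33Y differed from the wild-type rescue in 231 higher and 35 lower genes at day 0, among them 12 of 19 Wnt targets and 10 of 12 HOX genes, although CTNNB1 was lower in S33Y by -1.49. At day 1, 14 of 16 mesoderm genes and 10 of 13 BMP targets were higher in S33Y, HAND1 by 6.502 and WNT5A by 4.76, and FOXA2 was lower by -4.07. Between the stabilised forms, S33Y exceeded deltaN90 at day 1 in the retinoic acid enzyme ALDH1A2 (4.34), SOX2 (3.25) and CXCR4 (3.13) and was lower in 11 of 18 sterol genes and in SOX17 (-1.93).

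The mean of log2(FPKM + 1) over the 19 Wnt targets placed the lines in order. At day 0 it was 1.97 in the knockout, 2.09 in H1, 1.95 in H1 plus Dox, 2.00 in deltaC, 2.39 in the wild-type rescue, 2.41 in deltaN148, 2.54 in deltaN148C, 3.88 in deltaN90 and 4.18 in S33Y. At day 1 it was 1.93 in the knockout, 2.80 in H1, 2.82 in H1 plus Dox, 2.81 in deltaC, 2.86 in deltaN148C, 2.93 in deltaN148, 4.13 in the wild-type rescue, 4.93 in deltaN90 and 5.03 in S33Y.

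**Figure D2:**
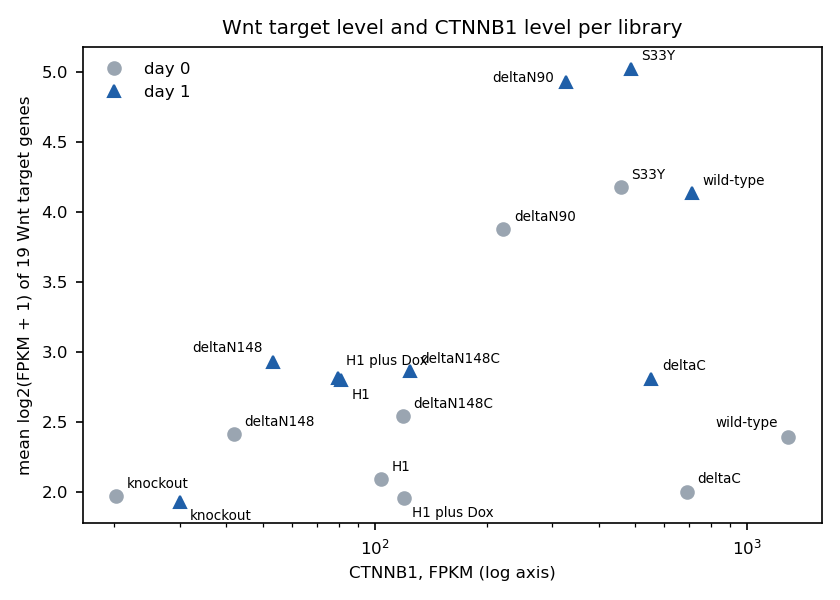
Each point is a library, placed by its CTNNB1 FPKM (log axis) and by the mean log2(FPKM + 1) of 19 Wnt target genes, with circles for day 0 and triangles for day 1. At day 0 the wild-type rescue had the highest CTNNB1 (1291) and a mean of 2.39, and S33Y had a CTNNB1 of 458 and a mean of 4.18.

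Across the 9 lines the change from day 0 to day 1 could be tested, each line being its own block. H1 and H1 plus Dox counted as separate lines, although both are H1 cells and the labels do not state whether they were separate cultures. If they were not, the tests here and below rest on fewer than 9 independent lines. H1 and H1 plus Dox also received CHIR99021 at day 1 and the other lines did not, so the tested change pools different treatments. In this test too streak, Nodal and BMP genes rose, and so did genes of the integrated stress response, while pluripotency, sterol and junction genes fell. By limma (two-sided, adjusted over all genes tested), 3566 genes rose and 2582 fell of 13633, 7258 having an unadjusted p under 0.05. The split depended on scaling: with libraries rescaled by median ratio 2807 rose and 3235 fell, by edgeR 2808 and 3260, and by DESeq2 3131 and 3233. Of the limma calls 5284 were made by edgeR in the same direction, and none in the opposite one. Leaving out single lines gave 2960 to 3659 rises and 2082 to 2653 falls. Without H1 there were 3404 rises and 2324 falls, and without H1 plus Dox 3268 and 2445.

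MIXL1 rose in 9 of 9 lines, by 4.11 ± 0.462 (log2, SE, n = 9 lines; limma adjusted p = 1.23e-04), as did TBXT (3.10 ± 0.419, adjusted p = 3.18e-04) and CER1 (4.995 ± 0.638, adjusted p = 2.33e-04). Of 17 streak genes 11 rose and none fell, with the same counts adjusted over the list alone, and they included WNT3 (2.55), FGF8 (3.30, up in 8 lines) and EOMES (2.50). Of 11 Nodal and activin genes 8 rose (8 adjusted over the list alone), LEFTY2 by 2.78 and LEFTY1 by 2.10, the last in 7 of 9 lines. Of 13 BMP targets 9 rose (10 adjusted over the list alone), including ID1 (1.21), ID2 (1.27) and MSX2 (1.45). Of 19 Wnt targets 7 rose and 1 fell (7 and 1 adjusted over the list alone), including SP5 (2.49), NOTUM (1.66) and NKD1 (1.30). AXIN2 did not pass (0.52, adjusted p = 0.201, up in 5 lines and down in 4). Of 15 endoderm genes 5 rose and 2 fell (6 and 2 adjusted over the list alone), with GATA4 at 2.11 and CYP26A1 at 1.70. SOX17 did not pass with limma (0.82, adjusted p = 0.102, up in 6 lines) and passed with edgeR (adjusted p = 3.16e-04) and DESeq2 (adjusted p = 0.0121). FOXA2 did not pass with limma (0.66, adjusted p = 0.392) or edgeR (adjusted p = 0.246) and passed with DESeq2 (adjusted p = 0.0244).

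Of 16 mesoderm genes 2 rose (1 adjusted over the list alone), HAS2 by 1.42 and TBX3 by 1.26. Of 17 integrated stress genes 14 rose (15 adjusted over the list alone), including DDIT3 (2.88), TRIB3 (2.59), DDIT4 (2.35) and CHAC1 (1.69). Of 17 FGF and ERK response genes 7 rose and 1 fell (8 and 1 adjusted over the list alone), IER3 by 1.46 and ETV5 by -0.90. Of 11 genes of epithelial-mesenchymal transition 4 rose (4 adjusted over the list alone), CDH11 by 1.61, and of 17 hypoxia genes 3 rose and 1 fell (3 and 1 adjusted over the list alone), PDK1 by 1.32. BHLHE40, a transcription factor of stress and circadian responses, rose by 2.63. TBX3 lost its call when any of the 6 rescue lines was left out (1.39 without deltaC, 1.34 without deltaN148, 1.28 without deltaN148C, 1.03 without deltaN90, 0.85 without S33Y and 1.22 without the wild-type rescue) and under rescaling (1.23).

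Among genes that fell, 11 of 24 pluripotency genes did and 1 rose (11 and 1 adjusted over the list alone), DNMT3B by -1.02, FOXD3 by -0.93 and TDGF1 by -0.83, each in 9 of 9 lines. POU5F1 (-0.18, adjusted p = 0.263), SOX2 (-1.12, adjusted p = 0.0775) and NANOG (0.15, adjusted p = 0.671) did not pass, though SOX2 passed without deltaC (-1.34) and NANOG without deltaN90 (0.41). Of 18 sterol genes 14 fell and none rose (16 adjusted over the list alone), INSIG1 by -1.80 and MSMO1 by -1.56. Of 17 junction genes 9 fell and 2 rose (10 and 2 adjusted over the list alone), PKP2 by -0.75 and VCL by -0.58, with CDH2, the N-cadherin gene, rising by 0.69. Of 17 proliferation genes 6 fell and 2 rose (6 and 2 adjusted over the list alone), PCNA by -0.59 and CCNB1 by -0.50. Of 9 early neural genes 5 fell and 1 rose (5 and 1 adjusted over the list alone), SOX3 by -1.71. The largest falls of all were those of MT1X (-2.36), IDO1 (-2.34), OR52A1 (-2.31), ACTA1 (-2.17) and SFRP1 (-2.15). CTNNB1 did not pass (-0.06, adjusted p = 0.767).

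For the remaining lists the counts of single genes were as follows. Of 9 neural crest genes 2 rose and 1 fell, of 12 amnion and trophoblast genes 4 rose and 4 fell, of 10 mesenchymal genes 1 rose and 2 fell, of 3 endothelial and blood genes 1 fell, of 15 p53 targets 1 rose and 3 fell, of 23 Wnt pathway components 7 rose and 5 fell, and of 14 housekeeping genes 3 rose and 3 fell. Adjusted over the list alone these counts were the same, except for 5 rises among the amnion and trophoblast genes and 2 falls among the p53 targets. None of 12 HOX and of 6 histone genes passed with limma.

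**Figure D3:**
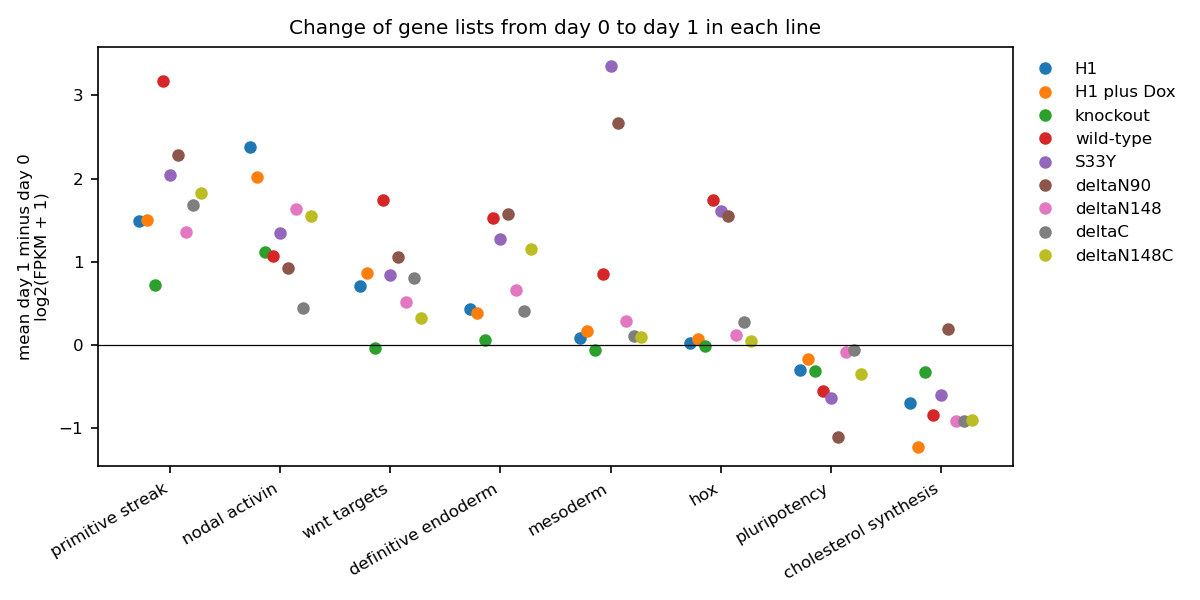
Each point is the mean day 1 minus day 0 difference of log2(FPKM + 1) over the members of a gene list in 1 line, with the 9 lines in colour and 8 lists along the axis. The streak list was above 0 in all 9 lines, the mesoderm list was highest in S33Y (3.35) and deltaN90 (2.67), and the sterol list was above 0 only in deltaN90 (0.19).

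As whole lists, 10 of 24 rose and 6 fell in an exact two-sided sign-flip permutation test over the 9 lines, whose smallest possible p is 0.0039 before adjustment. The test takes the 9 lines as independent, which is not known for H1 and H1 plus Dox. The streak list rose by 1.79 ± 0.684 (mean and SD over 9 lines, 9 up, adjusted exact p = 0.0104). Nodal and activin genes (1.39), integrated stress genes (1.07), BMP targets (0.95) and endoderm genes (0.83) rose in 9 of 9 lines at the same adjusted p. Wnt targets (mean over the 9 lines 0.76) rose in 8 lines, the exception being the knockout (-0.04), as did mesoderm genes (0.84 ± 1.27) and HOX genes (0.61), the knockout again being the exception (-0.06 and -0.01; adjusted exact p = 0.0134 for each). Transition genes (0.47, adjusted exact p = 0.0352, 7 lines up) and FGF and ERK genes (0.28, adjusted exact p = 0.0188, 8 lines up) also rose. The transition genes rose by 1.82 in S33Y and 1.30 in deltaN90, and 5 of the lines lay between -0.11 and 0.19. HOX genes rose by 1.74 in the wild-type rescue, 1.61 in S33Y and 1.55 in deltaN90, and the other lines were at 0.27 or less. Pluripotency genes (-0.39), early neural genes (-0.33), endothelial and blood genes (-0.37) and proliferation genes (-0.13) fell in 9 of 9 lines, and junction genes (-0.15) and sterol genes (-0.69) in 8. The neural crest, amnion and trophoblast, mesenchymal, Wnt pathway, p53, hypoxia, histone and housekeeping lists did not pass, with adjusted exact p from 0.0993 to 0.531. After rescaling 9 lists rose and 10 fell. That a list changed in some lines and not in the knockout was not tested.

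The last comparison asked which genes go with each part of the β-catenin protein, by fitting 3 features of the constructs to the 6 rescue lines at each day with limma (2 residual degrees of freedom, two-sided). Genes with a higher fitted level for loss of the N-terminal phosphorylation sites at day 0, the other features being held equal, were the posterior and streak factors CDX2 (log2 4.50, adjusted p = 0.00189), EVX1 (4.38) and GBX2 (3.23), the Wnt secretion factor WLS (4.11), and the Wnt feedback genes NKD1 (3.18), RNF43 (2.47), APCDD1 (2.67) and LEF1 (3.44, adjusted p = 0.0333). S33Y, which is changed at a site and not deleted, was counted as having lost the sites, as were deltaN90, deltaN148 and deltaN148C. Of these 4 lines, S33Y and deltaN90 had LEF1 at 16.7 and 20.35, and deltaN148 and deltaN148C at 1.35 and 2.69, against 1.34 in the wild-type rescue. In all 23 genes were higher and none lower, including 6 of 18 Wnt targets (11 higher and 1 lower adjusted over the list alone). At day 1, 8 were higher and none lower, including the mesoderm factor MESP1 (4.23), WNT5A (4.33), LGR5 (4.13), NRP1 (4.19) and LIX1 (4.88, adjusted p = 0.0222). Of 16 mesoderm genes 1 passed over all genes and 14 adjusted over the list alone. MIXL1 (5.82, adjusted p = 0.0588) and TBXT (5.38, adjusted p = 0.134) did not pass at day 0.

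With the N-terminal segment that deltaN148 lacks and deltaN90 keeps, 17 genes were higher and 2 lower at day 0, EVX1 (4.61), CDX2 (4.44), WLS (3.96) and GATA4 (2.64) being among the former, and 26 and 3 at day 1, with WNT5A (4.75), MESP1 (4.65), NRP1 (4.46), LGR5 (4.37) and the Notch ligand DLL3 (3.18). EVX1, CDX2, WLS, WNT5A, MESP1, NRP1 and LGR5 were also called for the lost phosphorylation sites, at sizes near these. No construct lacked the segment and kept the sites, so a gene high only in S33Y and deltaN90 is fitted with both features. For such genes the fit does not separate the segment from the sites, or from the 2 acting together. At day 1, 2 of 16 mesoderm genes passed over all genes and 15 adjusted over the list alone. Hypoxia genes were lower in 11 of 17 adjusted over the list alone on each day, and none passed over all genes. With the C terminus no gene passed with limma, at an unadjusted p under 0.05 of 112 genes at day 0 and 120 at day 1. By edgeR none passed either (88 and 138 unadjusted), and by DESeq2 1 and 3 did. Adjusted over the list alone with limma, 4 of 17 hypoxia genes and 1 of 17 streak genes were higher with the C terminus at day 1. The genes with the smallest p were CSAG2 at day 0 (1.64, adjusted p = 0.0878) and CDX1, a caudal factor, at day 1 (2.59, adjusted p = 1). The fitted C-terminus difference is the mean of 2 pairs, wild-type minus deltaC and deltaN148 minus deltaN148C. At day 1 many streak genes went opposite ways in these pairs, so the fit partly cancels such differences and counts them as residual spread. Simulated with equal effects in both pairs, the day 1 test recovered 100.0% at a log2 change of 2 and 48.9% at 1. Genes with a wider spread can go uncalled with 2 residual degrees of freedom. The absence of calls over all genes therefore does not show that no gene goes with the C terminus.

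These fits rest on few lines. In place of 19 genes at day 0, the N-terminal segment had 1190 without deltaC, 1058 without the wild-type rescue, 1005 without deltaN148C, 5 without deltaN90 and 3 without S33Y or deltaN148. In place of 29 at day 1 it had 325 without deltaN148C, 317 without the wild-type rescue, 289 without deltaC, 70 without S33Y, 4 without deltaN148 and none without deltaN90. The lost phosphorylation sites had, in place of 23 at day 0, 102 genes without the wild-type rescue, 58 without deltaC, 49 without deltaN148, 48 without deltaN148C and 5 without S33Y. In place of 8 at day 1 they had 127 without the wild-type rescue, 98 without deltaN148C, 86 without deltaN148, 83 without deltaC, and none without S33Y or deltaN90. The C terminus had, in place of none, 8 at day 0 without deltaC, 3 without the wild-type rescue and 1 without deltaN148 or deltaN148C, and at day 1 had 19 without deltaN148C and 18 without deltaN148. DESeq2 called 731 and 774 genes for the N-terminal segment and 208 and 595 for the phosphorylation sites, whereas edgeR called 3 and 3, and 20 and 1. With no filter none passed for any of the 3 features on either day.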

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

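The tests in this part were chosen only after the result was seen, except the tests of the share of the knockout difference undone in the wild-type rescue and of its highest value over the 6 rescue lines, which were fixed before those shares were computed.

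Of 24 gene lists examined for a line far from the other 8 in its day 1 minus day 0 mean, 2 had such a line, and chance gives about 1 in 20. The amnion and trophoblast list changed by 0.929 in S33Y against at most 0.314 elsewhere, a gap of 0.583 of the whole range, above the critical value of Dixon's test for 9 values. The p53 target list changed by 0.288 in H1 and by -0.051 or less in the other lines, a gap of 0.613 of the range. With 1 library per group the rule, meant for replicates of a group, was applied across the 9 lines.

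Of 327 listed genes 3 moved by at least 1 in H1 and H1 plus Dox and in the opposite direction by at least 0.5 in the knockout, a minimum set after the data were seen. CYP26A1 changed by -0.688 in the knockout (FPKM 2.64 to 1.26) and went from 3.17 to 10.5 in H1. DUSP6 changed by 1.301 (27.1 to 68.2) and went from 18.6 to 6.83 in H1. HIST1H2BK changed by -1.121 (123.7 to 56.3) and went from 14.4 to 56.0 in H1. Whether the lines differ was not tested for these genes, since each value is 1 library, and H1 and H1 plus Dox also received CHIR99021 at day 1.

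Most of the genes that differed in the knockout at day 0 stayed different in the wild-type rescue, with less than 0.25 of the difference undone in 96 of 141. In the wild-type rescue, which had 1291 FPKM of CTNNB1, the median share of the difference undone was 0.115 over 141 genes other than CTNNB1, with 19 genes at 0.5 or more, which argues against an effect that β-catenin reverses within its day of doxycycline. Without the MTRNR2L genes the count was 146 against 142. These genes held 0.76% to 3.22% of the counts of a library, too little to shift other genes by much, so a similar count was bound to result. Other abundant transcripts were not examined. A lasting difference of the knockout clone may be the source, but the highest median over the 6 rescue lines was 0.353, in deltaN148, where 58 of the genes had 0.5 or more undone and a median under 0.25 had been predicted for all 6. With 1 knockout line, a lasting effect of β-catenin loss and a difference of the clone cannot be told apart, and the shares assume that the rescue clones came from this knockout clone, which the labels do not state.

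The level of Wnt targets at day 0 differed between rescue lines in another order than CTNNB1. The mean of the list in the wild-type rescue minus deltaN90 was -1.487, whereas the amount of CTNNB1 transcript would put it above 0, and the H1 pair differed by 0.138. Loss of the phosphorylation sites alone would raise deltaN148 and deltaN148C (2.542) above the wild-type rescue (2.390), and the difference was 0.023 in the former. Loss of the sites with the segment kept that separates deltaN90 from deltaN148 may also explain it, since the lower of S33Y and deltaN90 exceeded the highest of the other 4 lines by 1.335. The explanations by the sites alone and by the sites with the segment cannot be told apart, because CTNNB1 was lower in deltaN148 and deltaN148C (41.8 and 119) than in deltaN90 (222) and the wild-type rescue (1291), and the protein was not measured here.

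Hypoxia and glycolysis genes were high in deltaN148. A passing state of the day 0 culture would leave day 1 within the difference of the H1 pair (at most 0.557 on either day), and the day 1 median was 1.249. The MTRNR2L genes held 1.21% of the counts in deltaN148 and 0.99% in the knockout at day 0. Shares this small allow a shift of only 0.0033, so a low value was bound to result. Other abundant transcripts were not examined. Loss of the segment that separates deltaN90 from deltaN148 might be the source, but deltaN148C, which lacks it too, had 0.437 at day 0 (0.663 at day 1), short of the 0.557 that was required, and the wild-type rescue and S33Y, which keep it, had 0.528 and 0.478 at day 1. The construct and a lasting property of the line cannot be told apart with 1 line each, and no further explanation was tested.

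For the change between days over the 9 lines, 6148 genes passed with the real days, and the highest of the other exchanges of days within lines gave 1738. Of 100 exchanges drawn from all possible ones, the real split included, only the real split gave as many genes. The smallest share this test can give is 1 in 100. It does not separate the induction from anything else that differed between the days, such as the medium.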

How the results depend on the processing

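The alternatives with edgeR, DESeq2, without the MTRNR2L genes and with the day 1 level for recovery were chosen after the data were seen, and the others before. Of 312 values of the 37 results that answer a comparison, 215 stayed within their limit (1.5 times for counts), 96 moved and 1 reversed. Of 468 values of genes named between single libraries 415 stayed and 53 moved, all with the pseudocount of 0.5, and none reversed. Of 1614 values of the 96 genes named in the day effect 1548 kept their call, 61 lost it (22 genes, mostly without the line block or without a line), 5 gained it and none reversed. The gains were SOX17 with edgeR and DESeq2, FOXA2 with DESeq2, SOX2 without deltaC and NANOG without deltaN90. Outside the block and left-out lines, calls were lost for TBX3, EGR1 and FDXR with no filter, for TBX3, EGR1 and MMP2 with rescaling and for MMP2 with edgeR. A single wild-type reference was run for counts and recovery and not for the genes named between single libraries. With 1 library per group, depth was not the limit for abundant genes, and genes near an FPKM of 0.07 rested on about 3 counts.

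With H1 plus Dox as the only wild-type reference, the day 1 response had 574 higher and 315 lower genes, the knockout had 78 higher genes at day 0, and there were 224 β-catenin-dependent genes. Median recovery was then 0.242 in the wild-type rescue and reversed to -0.023 in deltaN90. With H1 as the only reference, 432 response genes were lower, the knockout had 188 higher and 738 lower genes at day 0, and the wild-type rescue recovered 0.222. By construction a single reference asks for less than both. With the day 1 level against the H1 day 0 level, recovery was 0.396 in S33Y, 0.680 in deltaN90 and 0.560 in deltaN148C.

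With a pseudocount of 0.5, which by construction widens differences of low values, 225 response genes were lower and 173 genes were lower in the knockout at day 0. Rescue against knockout totals at day 0 were 129 in the wild-type rescue, 639 in deltaN90, 753 in deltaN148, 193 in deltaC and 208 in deltaN148C, and 314 in deltaN148C at day 1. The H1 pair differed in 469 genes at day 0 and 26 at day 1. At day 1, 11 genes went with the N-terminal segment (the residues that deltaN148 lacks and deltaN90 keeps) and 2 with the lost phosphorylation sites.

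With a mean FPKM of at least 5, fewer genes were tested. Then 87 response genes were lower, the knockout had 24 higher and 50 lower genes at day 0 and 304 lower at day 1, 56 genes were β-catenin-dependent, and recovery was 0.550 in deltaN148. Totals against the knockout at day 1 and day 0 were 403 and 42 in the wild-type rescue, 423 and 162 in S33Y, 929 and 242 in deltaN90, 238 and 288 in deltaN148, 254 and 60 in deltaC, and 131 and 71 in deltaN148C. The H1 pair differed in 144 and, at day 1, 2 genes, 1686 genes fell between days, and 0 genes went with the N-terminal segment or with the phosphorylation sites at day 1.

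The tests of construct features moved most, and the cause was not tested. With no filter, 0 genes went with the N-terminal segment or with the phosphorylation sites on either day. With 2 features, 1 gene went with the C terminus at day 0 and 0 with the N-terminal segment on each day. By DESeq2, 1 and 3 genes went with the C terminus at day 0 and day 1, 731 and 774 with the N-terminal segment, and 208 and 595 with the phosphorylation sites. By edgeR, 3 and 3 went with the N-terminal segment, and 1 with the phosphorylation sites at day 1. With rescaled libraries 44 genes went with the N-terminal segment at day 1, and 10 gene lists fell between days. With the day difference as outcome, 5 genes went with the N-terminal segment and 109 with the phosphorylation sites.

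Leaving out each rescue line in turn gave 0 to 8 genes for the C terminus at day 0 and 0 to 19 at day 1. It gave 3 to 1190 for the N-terminal segment at day 0 (3 without deltaN148 or S33Y, 1190 without deltaC) and 0 to 325 at day 1 (0 without deltaN90, 325 without deltaN148C). It gave 5 to 102 for the phosphorylation sites at day 0 (5 without S33Y, 102 without the wild-type rescue) and 0 to 127 at day 1 (0 without deltaN90 or S33Y, 127 without the wild-type rescue). Some of these fits leave a feature with 1 line, assumed to vary like the rest. For the change between days, the counts without single lines and without the block stayed within 1.5 times. No paired analysis by replicate number was possible because each group has 1 library. The line was the block of the day test.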

Other observations

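Nodal pathway genes came apart at day 1. NODAL was at 217 FPKM in the wild-type rescue and 90.3 in deltaC, yet its feedback antagonist LEFTY2 was at 9.43 and 10.6 there, against 274 in H1, 140 in the knockout, 101 in deltaN148 and 95.9 in deltaN148C. LEFTY1 was at 17.2 and 12.2 in the same lines against 169 in H1 and 210.4 in the knockout, and at 25.9 in deltaN90. CER1 was at 1657 in deltaN90 and 787 in S33Y and between 17.6 and 155 in the other lines. FOXA2 went from 10.2 at day 0 to 0.46 at day 1 in S33Y and from 0.17 to 23.5 in the wild-type rescue. The chemokine receptor CXCR4, a surface marker of endoderm, was at 30.2 in S33Y at day 1 and at 2.57 or less in the other lines.

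SOX2 at day 1 ranged from 1.31 in deltaN90 to 140.5 in deltaC, and its highest day 1 value outside deltaC was 118 in H1 plus Dox. The peptide hormone gene APELA was at 32.6 in deltaC at day 1 and at 0.92 in deltaN90, 1.33 in S33Y and 3.13 in the wild-type rescue. The metallothionein MT1E was at 224 in deltaC at day 1 and at 80.6 or less in the other lines of that day. The sterol regulator INSIG1 went from 33.2 to 31.9 in deltaN90, and from 20.4 to 5.39 in the wild-type rescue and 21.6 to 4.52 in S33Y. LCP1 was at 144 and 182 in deltaN148 and 121 and 115 in deltaN90, against 29.03 and 30.8 in the knockout, 6.01 and 14.03 in S33Y and 3.80 and 3.48 in H1.

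Several genes separated H1 and H1 plus Dox from every line derived from the knockout, on both days. IAH1 was between 5.75 and 9.53 in the 4 libraries of H1 and H1 plus Dox and between 0.09 and 0.36 in the others, and ZNF492 between 5.29 and 8.39 against 0.04 to 0.20. CDK10 was between 10.4 and 13.9 against 0.53 to 2.48. CSAG2 and IFIT1, in contrast, separated the rescue lines from the knockout: at day 1 IFIT1 was at 54.7 in the knockout, 56.8 in H1 and between 10.6 and 24.7 in the 6 rescue lines. CSAG2 was at 61.6 in the knockout, 53.6 in H1 and between 9.93 and 29.8 in the rescue lines.

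The genes in these paragraphs were picked from those named by the rule after their values were seen, and the differences were not tested.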
